A study of Rattus norvegicus with 91 samples.

How the data were processed

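Ventral tegmental area tissue of 91 rats was measured on 1 Affymetrix array each, per the labels. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy column, and 25 ng of total RNA per array was amplified in 2 cycles and labelled as biotin cRNA. The deposited values are log2 signals of 31099 probe sets made by the authors with RMA, per the submitters' processing notes, which name the method. RMA is a method that corrects background, normalizes quantiles over the arrays of a run and summarises the probes of a probe set. Its version and the sets of arrays it was run on are not given in the sources used here. The table had 0 columns without a sample in the labels. Arrays normalized together have nearly the same distribution. The distributions here were cut into 5 sets by clustering, and levels were not compared between lines of different pairs.

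Probe sets were named from the platform annotation, in which 20826 had 1 gene symbol, 436 several and 9780 none, and the 57 control probe sets were left out. Of the single-gene probe sets, 20758 matched by gene ID to a reference table of the GRCr8 assembly, which changed 0 symbols. That table was used only for names and for which genes neighbour each other. For each of 14217 genes the single-gene probe set with the highest mean over all arrays was used. A gene was tested if the highest of its 10 line means was at or above the 40th percentile of all values, 7.02 on the log2 scale, which left 11082 genes.

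Samples were grouped by the line and animal in their titles. All arrays entered 1 limma fit (lmFit and eBayes) of 10 line means with 81 residual degrees of freedom. The contrasts were the high-consumption minus the low-consumption line in each pair, their average over the 5 pairs, and a moderated F test with 4 numerator degrees of freedom for whether the difference depends on the pair. Tests were 2-sided, with Benjamini-Hochberg adjustment within a contrast, and a gene was called at an adjusted p under 0.05. A fold of 1.5 was set as a further threshold. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation beside it, and with fry, whose p tests whether the genes of a list move on balance 1 way. Adjustment was over the 31 lists with at least 3 tested genes within a contrast. Overlaps of calls were set against the product of the shares called, as for independent lists. Array measures were the median, interquartile range, mean correlation with the line, and 3'-minus-5' signals of Gapdh and actin controls. These measures and list means were compared within pairs by exact permutation tests, or with 100000 resamples where both lines had 10 arrays. They were 2-sided and adjusted over the 5 pairs for each measure or list, not over the lists. Of 155 permutation tests of list means, 15 had an unadjusted p under 0.05 and 10 an adjusted p under 0.05. Technical sets were made by clustering the quantiles of the arrays and cutting the tree at 5 sets, a number that was chosen and not estimated. Complete and average linkage gave the same place of the array labelled AA 1 as Ward's method, and the places of the other arrays were not compared.

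The tests, gene lists and most alternatives were fixed before the data were examined, as was the rule for named genes. The rule took, for the average, the 12 highest and 12 lowest called genes with 1 sign in all pairs. For each pair it took the 8 highest and 8 lowest called genes, for the interaction the 10 genes called in opposite directions with the widest range, and for each list up to 4 called members, with Th, Slc6a3, Ddc and Slc18a2 whatever their result. Genes called the same way in at least 4 pairs would also have been named, and there were none. Predicted symbols were passed over.

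Alternatives were no filter or the 60th percentile (8.58), quantile normalization over all arrays, centring of each array, each pair fitted alone, an intensity trend with a robust prior, array weights, other choices of probe sets, a replicate block, the fold threshold, other averages and each array left out. The 5 sets as terms of the model, the HAD and LAD arrays alone, the average of both HAD/LAD pairs, the single set of most arrays labelled AA and ANA, and leaving out each array for the pairs and their gene lists were chosen after seeing the data. The fit was tested on simulated data with 50 genes changed per size. The simulated noise was normal, independent between genes, and had 1 residual spread per gene for all lines. At log2 sizes of 0.25, 0.5, 1 and 2 the fit recovered 54%, 96%, 98% and 100% for HAD1/LAD1, and 62%, 92%, 94% and 100% for HAD2/LAD2, and 10 of 184 calls were false in each. These rates do not cover correlated genes, outlying arrays or lines with a wider spread, which the real data hold. Versions were R 4.3.3, limma 3.58.1, 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.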

Results

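Gene expression was measured in the ventral tegmental area, the midbrain region that holds the dopamine neurons projecting to the ventral striatum and cortex, of rats from 10 lines. The lines form 5 pairs, HAD1/LAD1, HAD2/LAD2, P/NP, AA/ANA and sP/sNP, and in each pair the line named first was selectively bred for high and the line named second for low alcohol consumption. The labels give 91 arrays, 1 per animal: 8 HAD1, 10 LAD1, 8 HAD2, 9 LAD2, 9 P, 10 NP, 10 AA, 10 ANA, 8 sP and 9 sNP. Values were log2 signals of 31099 Affymetrix probe sets, from 3.71 to 16.2, and 11082 genes were tested with 1 probe set each. The number of arrays per line limits the precision. The median standard error of a line difference ran from 0.0663 (AA/ANA) to 0.0721 (HAD2/LAD2 and sP/sNP) on the log2 scale. Y-linked Eif2s3y was between 10.6 and 12.3 on all arrays, and the highest Xist signal was 6.6.

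Clustering of the value distributions, cut at 5 sets by choice, grouped the arrays mostly by labelled pair. The sets of the HAD2/LAD2 and HAD1/LAD1 arrays overlapped in lower quartile (5.99 to 6.12 and 5.97 to 6.05) and in highest value (15.03 to 15.13 and 15.07 to 15.32). So did the sets of 17 and 19 arrays described below (lower quartile 5.73 to 5.83 and 5.68 to 5.74), which makes the borders between these sets less certain. All 17 HAD2 and LAD2 arrays lay in 1 set and all 18 HAD1 and LAD1 arrays in another. A set of 20 arrays held the 9 labelled P, the 10 labelled NP and 1 labelled AA. A set of 17 held 8 labelled AA and 9 labelled ANA, and a set of 19 held 1 labelled AA, 1 labelled ANA, 8 labelled sP and 9 labelled sNP. The 3'-minus-5' log2 signal of the Gapdh control, a measure of RNA and labelling quality, differed far more between pairs than within them. Its line means were 1.89 and 1.78 in HAD1 and LAD1, 3.42 and 3.58 in HAD2 and LAD2, 0.136 and 0.144 in P and NP, 0.501 and 0.567 in AA and ANA, and 0.389 and 0.395 in sP and sNP. Levels were therefore compared only between the 2 lines of a pair. Since 3 arrays labelled AA or ANA lay apart from the other arrays of their label, the groups outside the HAD/LAD lines are named as arrays labelled with a line. Whether the labels of all 56 arrays outside the HAD/LAD lines match their values is open. Rotated by 19 places against the values, these labels called 1468 genes over P/NP, AA/ANA and sP/sNP, against 326 as given. Every result of these pairs therefore rests on labels that may be misplaced.

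**Figure D1:**
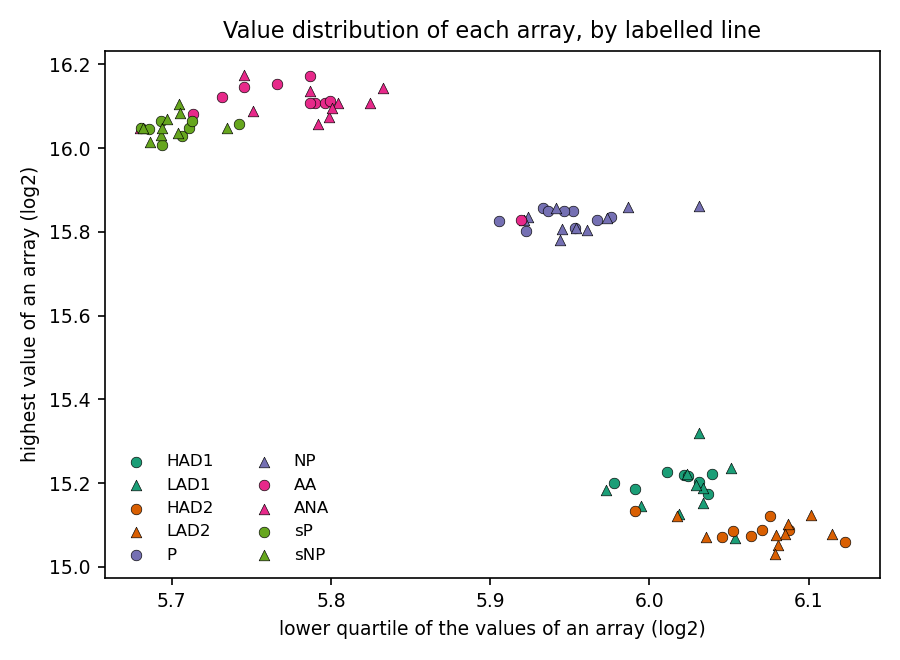
Lower quartile (x axis, log2 signal) and highest value (y axis, log2 signal) of each of the 91 arrays, coloured by labelled pair, with circles for the high-consumption and triangles for the low-consumption line. The HAD and LAD arrays have highest values between 15.03 and 15.3, those labelled P and NP between 15.8 and 15.9, and 1 array labelled AA lies among the latter.

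The comparison of HAD2 with LAD2, as of each pair, asks which genes differ between lines bred in opposite directions. The MHC class I gene RT1-T24-4 was 3.54 ± 0.53 (log2 difference ± standard error, 8 HAD2 and 9 LAD2 arrays) higher in HAD2, the largest difference of this pair. Fcrl2, a member of the Fc receptor-like family, was 2.106 ± 0.28 higher, the interferon-inducible gene Ifi27 1.41 ± 0.15 higher and the MHC class I gene RT1-S3 1.14 ± 0.21 higher. RT1 genes have near-identical copies, so which copy the signal came from is uncertain. The mitotic kinesin gene Kif15 (1.61 ± 0.19), the G-patch domain gene Gpatch11 (1.19 ± 0.08) and the anoctamin gene Ano5 (1.19 ± 0.14) were also higher in HAD2. The lens galectin-related gene Grifin was 1.84 ± 0.59 higher, with an adjusted p of 0.0489, and this call was lost without the filter on dim genes, after further normalization or centring of the arrays and with a robust prior. Lower in HAD2 were Slc3a1, the heavy subunit of a cystine and dibasic amino acid transporter (-2.13 ± 0.22), the sialic acid-binding lectin Siglec5 (-1.93 ± 0.29) and Pnlip, pancreatic lipase (-1.86 ± 0.10, adjusted p 2.63e-28). The RNA-binding protein gene Elavl1 (-1.84 ± 0.23), the mitochondrial trafficking adaptor gene Trak2 (-1.45 ± 0.17), the metabotropic glutamate receptor gene Grm5 (-1.43 ± 0.24), the iron-sulfur cluster assembly gene Isca1 (-1.39 ± 0.10) and the desmosomal gene Pkp1 (-1.32 ± 0.25) were lower too. A further probe set of Elavl1, Trak2 and Isca1 above the floor gave differences of 0.06, 0.14 and 0.05, against the sign of the first. The further probe sets of Gpatch11 and RT1-S3 kept the sign, with differences of up to 0.53 and 1.04.

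In the lists fixed before the data were examined, heat shock and antigen presentation genes stood out in HAD2/LAD2. Of 22 heat shock and chaperone genes, 4 rose and none fell (6 and 0 adjusted over the list alone): Hspa1a by 0.78 ± 0.17, Hspa4 by 0.70 ± 0.15, Dnajb1 by 0.22 ± 0.06 and Dnajb4 by 0.18 ± 0.04. The list shifted upward by camera (adjusted p = 0.012) and by fry (adjusted p = 0.00303), with adjusted p = 0.999 with an estimated correlation in camera. Without array HAD2 5, a check chosen after seeing the data, the camera adjusted p was 0.0963. The calls of Hspa4 and Dnajb1 were lost when the pair was fitted alone. Of 30 genes of antigen presentation and interferon response, 4 rose and 2 fell (7 and 2 adjusted over the list alone). RT1-T24-4, Ifi27 and RT1-S3 rose as given, and the immunoproteasome subunit gene Psmb8 rose by 0.54. The MHC class II beta chain gene RT1-Bb was lower (-0.72 ± 0.17), as was RT1-CE5 (-0.64). This list also shifted upward by camera (adjusted p = 0.0194), with adjusted p = 0.999 with an estimated correlation and 0.0801 by fry. Without HAD2 6, HAD2 7 or HAD2 8 the camera adjusted p was 0.0686, 0.0535 or 0.0623. In glutamate signalling, Grm5 fell as given and the NMDA receptor subunit gene Grin3a rose by 0.86 ± 0.16, while the other 28 of 30 genes were not called. Of 20 endothelial and pericyte markers 3 rose and 2 fell, among them the drug efflux pump gene Abcb1a (0.60 ± 0.12), Abcc9 (0.44 ± 0.09), the pericyte marker Rgs5 (0.35 ± 0.09) and the angiopoietin receptor gene Tek (-0.37 ± 0.07). A further probe set of Abcb1a gave 0.13 and one of Abcc9 0.16. The mean of these markers was 0.08 higher in HAD2 (exact permutation test, adjusted p = 0.0419), while their median difference was -0.003 and camera gave an adjusted p of 0.916. The mean of 3 measured hypothalamic and mammillary markers was lower (-0.19, exact permutation test, adjusted p = 0.0378). None of them was called, and camera gave an adjusted p of 0.771. Here and below, the permutation adjusted p of a list mean covers the pairs and not the lists. Single genes were called in other lists: the microglial receptor gene P2ry12 (0.54 ± 0.16), the myelin gene Opalin (-0.33 ± 0.10), Adcy9 (0.52 ± 0.10), Gsto1 (-0.38 ± 0.11), Mgst2 (-0.39 ± 0.12), Kcnd2 (-0.42 ± 0.11) and the ATP-gated channel gene P2rx4 (0.38 ± 0.10).

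In total, 605 genes were called between HAD2 and LAD2 by limma at an adjusted p under 0.05, 372 higher and 233 lower in HAD2, of which 105 differed by at least 1.5-fold and 28 by at least 2-fold. At an unadjusted p under 0.05 there were 1692 genes, where 554 of the tested genes would pass by chance. The share of calls that were higher was 61.5% as deposited and 46.7% (291 higher, 332 lower) after centring each array on its median, so the balance of directions among small differences is not settled.

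Between HAD1 and LAD1 the largest difference was in another gene. Mis18a, which encodes a centromere licensing factor, was lower in HAD1 by the widest margin of the pair (-3.22 ± 0.20, 8 HAD1 and 10 LAD1 arrays, adjusted p 2.79e-23), with signals of 7.21 ± 0.51 (SD) in HAD1 and 10.4 ± 0.99 in LAD1. Higher in HAD1 were the cytochrome P450 gene Cyp2j10 (2.43 ± 0.28), the amylase gene Amy1 (2.28 ± 0.34), Nrg1, the neuregulin ligand of ErbB receptors (1.99 ± 0.29), RT1-T24-4 (1.82 ± 0.52), Kif15 (1.65 ± 0.19), Elavl1 (1.63 ± 0.23), the protease-like gene Prss35 (1.387 ± 0.34) and Pkp1 (1.14 ± 0.24). Lower were Grifin (-2.38 ± 0.58), the phospholipase gene Pla2g4e (-1.24 ± 0.14), the methyltransferase gene Etfbkmt (-1.10 ± 0.14), Inhca (-1.08 ± 0.27), the epithelial transcription factor gene Grhl3 (-1.07 ± 0.18), the DNA repair gene Mgmt (-1.06 ± 0.15) and Rrs1-ps9 (-1.05 ± 0.17). The calls of RT1-T24-4 and Prss35 were lost when the pair was fitted alone. All 3 further probe sets of Nrg1 above the floor kept its sign, with at most 0.61, whereas that of Elavl1 gave -0.11.

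No list passed camera in HAD1/LAD1, and called members went in both directions. Of 30 glutamate genes, 1 rose and 2 fell: the postsynaptic scaffold gene Homer2 by -1.02 ± 0.27 and the metabotropic receptor gene Grm2 by -0.50 ± 0.14, while Dlg4, which encodes PSD-95, rose by 0.35 ± 0.09 (a sign that turned to -0.007 with the mean of its probe sets). The list had a median of 0.04, a mean of -0.03 and an adjusted p of 0.967 by camera. Of 16 candidate genes from earlier work on alcohol-preferring rats, none rose and 3 fell, Homer2, Grm2 and the glutathione transferase gene Gsta4 (-0.96 ± 0.19), with a median of 0.03, a mean of -0.08 and an adjusted p of 0.542 by camera. The call of Homer2 was lost when the pair was fitted alone. Of 30 antigen presentation and interferon genes, 6 rose and 1 fell (8 and 3 adjusted over the list alone), with camera adjusted p = 0.131. Ifi27 rose by 0.89 ± 0.15, RT1-S3 by 0.85 ± 0.20, Psmb8 by 0.59 and the interferon regulatory factor gene Irf7 by 0.52, and RT1-Bb fell (-0.74 ± 0.17). The mean of this list was 0.18 higher in HAD1 (exact permutation test, adjusted p = 0.0313). The mean of 6 endocannabinoid genes was 0.13 higher in HAD1 (exact permutation test, adjusted p = 0.00686), with a median difference of 0.04. In this list 1 gene was called, the capsaicin receptor gene Trpv1 (0.63 ± 0.19), which made up most of the mean difference. The adjustment did not cover the lists, and 10 of 155 permutation tests of list means passed in all. In the cyclic AMP list 3 genes fell and none rose, among them the kinase anchor gene Akap5 (-0.82 ± 0.24) and Prkar2a (-0.31 ± 0.08). The myelin genes Enpp2 (0.34 ± 0.10) and Mobp (0.30 ± 0.08) rose, the microglial receptor gene Cx3cr1 fell (-0.33 ± 0.07), and of the endothelial markers Abcb1a fell (-0.53 ± 0.11, with -0.07 at a further probe set) and Tek rose (0.39 ± 0.07). Enpp2 was not called with the pair fitted alone, nor Mobp and Prkar2a with the mean of their probe sets.

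There were 427 called genes between HAD1 and LAD1, 231 higher and 196 lower in HAD1, of which 70 differed by at least 1.5-fold and 18 by at least 2-fold, and 1352 passed an unadjusted p of 0.05. After quantile normalization 205 were higher and 232 lower. The array labelled LAD1 37 had signals close to those of HAD1 at most of the named genes, and the count was 580 without it, with 423 of the 427 calls kept. With the pair fitted alone the count was 341, and 591 without that array. The mean correlation of an array with others of its line was 0.9918 in HAD1 and 0.9895 in LAD1 (exact permutation test, adjusted p = 0.0464), the only 1 of 25 tests of array measures that passed.

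**Figure D2:**
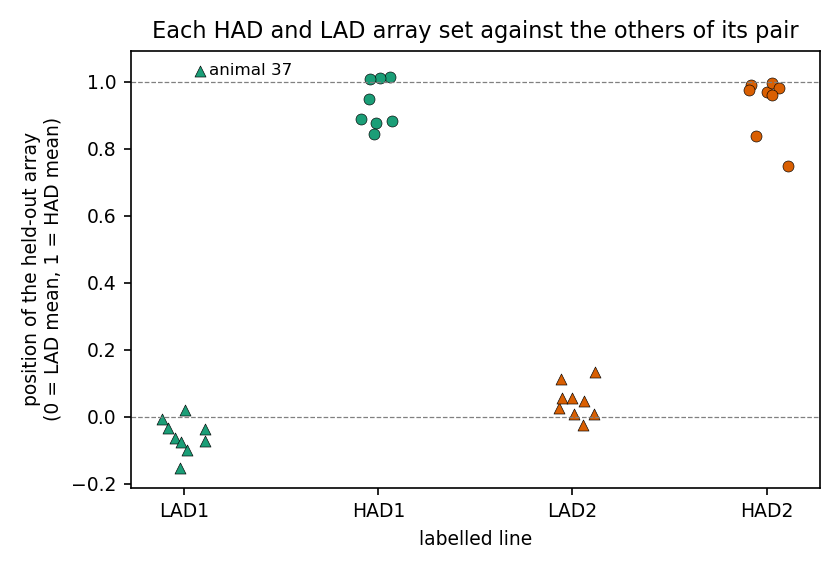
Position of each HAD and LAD array (y axis, no unit) between the mean of the other arrays of the low-consumption line (0) and of the high-consumption line (1), over the genes called in its pair without that array, by labelled line (x axis). HAD1 arrays lie between 0.843 and 1.01 and 9 LAD1 arrays between -0.15 and 0.02, while the array labelled LAD1 37 lies at 1.03. HAD2 arrays lie between 0.748 and 0.9954 and LAD2 arrays between -0.02 and 0.13.

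No single marker of dopamine neurons was called in any pair in the fit of all arrays. Th, the rate-limiting enzyme of dopamine synthesis, was 14.3 ± 0.17 (SD) in HAD1 and 14.3 ± 0.26 in LAD1, and 13.9 ± 0.28 in HAD2 and 13.9 ± 0.17 in LAD2. The dopamine transporter gene Slc6a3 differed by -0.06 ± 0.44 (standard error) in HAD1/LAD1 and 0.08 ± 0.45 in HAD2/LAD2, and the vesicular transporter gene Slc18a2 by 0.00 ± 0.43 and 0.21 ± 0.44. Ddc, which encodes the decarboxylase of dopamine synthesis, differed by -0.69 ± 0.33 in HAD1/LAD1 (adjusted p = 0.366) and was called there when the pair was fitted alone (adjusted p = 0.0141). None of the 20 dopamine neuron markers was called in any pair in that fit. As a list they were higher in the arrays labelled P by camera without array P 10, a check chosen after seeing the data (adjusted p = 1.46e-08, and adjusted p = 0.141 with an estimated correlation). That check kept the array labelled NP 8, whose Th was 8.23 against 11.64 to 14.88 in the others labelled NP. It therefore left out a low array on 1 side only. The arrays labelled P and NP varied much more, with Th at 13.2 ± 1.918 (SD) and 12.9 ± 2.107, and this spread enters the standard errors that all pairs share.

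The HAD1/LAD1 and HAD2/LAD2 pairs, known as replicate selections, shared called genes in both directions. Of 118 genes called in both, 40 were higher and 19 lower in the high-consumption lines of both, against 11.9 in the same direction by chance from independent lists, and 59 went in opposite directions, against 11.4 by chance. RT1-T24-4, Kif15, Ifi27, Gpatch11, RT1-S3 and Psmb8 were higher and RT1-Bb and Trak2 lower in both HAD1 and HAD2, while a further probe set of Trak2 was higher in both (0.23 and 0.14). Grifin, Elavl1, Pkp1, Etfbkmt, Tek, Abcb1a and P2rx4 went in opposite directions: Elavl1 was 1.63 higher in HAD1 and fell by 1.84 in HAD2, and Tek was 0.39 higher and fell by 0.37. Across all genes tested, which are not independent replicates, the log2 differences of both pairs had a Pearson's r of 0.03 and a Spearman's rho of 0.04. The difference itself differed between the HAD/LAD pairs in 459 genes by limma, 204 with the larger value in HAD1/LAD1 and 255 in HAD2/LAD2. In that contrast the 17 myelin and oligodendrocyte genes shifted toward HAD1/LAD1 by camera (adjusted p = 0.0165, and adjusted p = 0.989 with an estimated correlation).

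**Figure D3:**
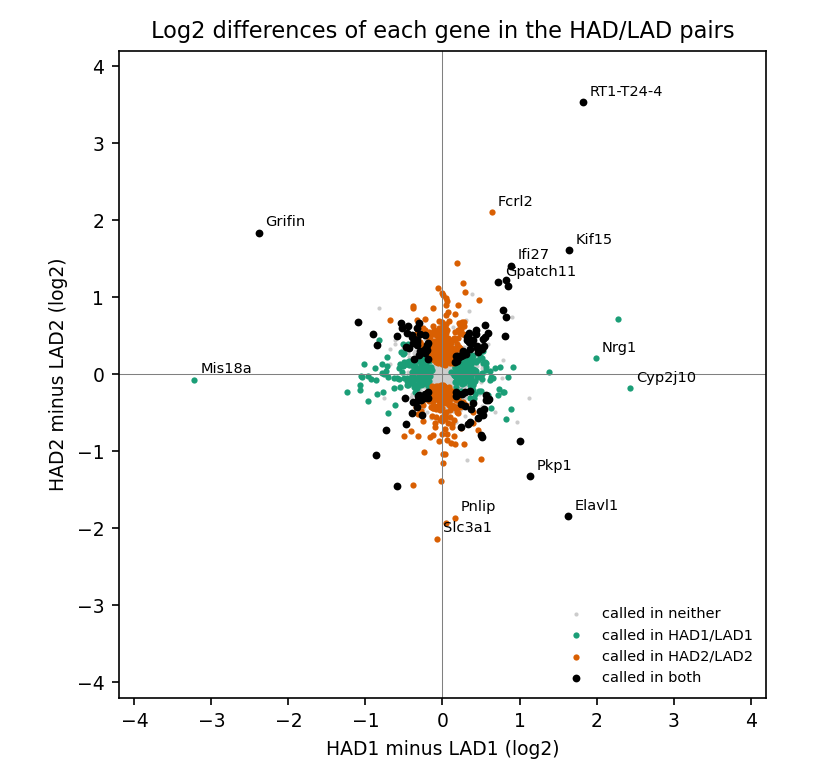
Log2 difference of each of the 11082 genes tested in HAD1 minus LAD1 (x axis) against HAD2 minus LAD2 (y axis), with points coloured by the pairs in which a gene was called. The 118 black points, called in both pairs, lie in all quadrants, 59 with the same and 59 with opposite signs.

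The mean of both HAD/LAD differences, an alternative chosen after seeing the data, called 573 genes, 366 higher and 207 lower. Of the 30 antigen presentation and interferon genes 9 rose and 3 fell (11 and 3 adjusted over the list alone), led by RT1-T24-4 (2.68 ± 0.37), Ifi27 (1.15 ± 0.10), RT1-S3 (0.99 ± 0.14) and RT1-CE16 (0.82 ± 0.21), with RT1-Bb lower (-0.73). This list shifted upward by camera (adjusted p = 0.00148, and adjusted p = 0.989 with an estimated correlation) and by fry (adjusted p = 0.0131). Of 22 heat shock genes 4 rose and none fell (7 and 0 adjusted over the list alone), Hspa1a by 0.47 ± 0.12, the small heat shock protein gene Hspb1 by 0.46 ± 0.13, Hsp90b1 by 0.15 ± 0.05 and Dnajb1 by 0.15 ± 0.04. They shifted by camera (adjusted p = 0.0139, and adjusted p = 0.989 with an estimated correlation) and by fry (adjusted p = 0.0095). Without HAD2 5 the camera adjusted p of this list was 0.0952, and the calls of Hsp90b1 and Dnajb1 were lost after centring the arrays. Gsta4 (-0.65 ± 0.14) and Cx3cr1 (-0.25 ± 0.05) were lower and P2ry12 (0.38 ± 0.11) and Gpx1 (0.22 ± 0.07) higher, of which Gpx1 was not called after centring.

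Between the arrays labelled AA and ANA the largest differences were in Enpp1 and Fcrl2, both lower in those labelled AA. The choline-specific phosphodiesterase gene Enpp6, a marker of forming oligodendrocytes, was 1.3504 ± 0.19 higher in the arrays labelled AA (10 and 10 arrays), and the nucleotide pyrophosphatase gene Enpp1 was lower (-1.56 ± 0.16, adjusted p 9.26e-12). Also higher were Prss35 (1.2101 ± 0.32), the condensin gene Ncaph (1.14 ± 0.16), the glycine receptor gene Glra1 (1.14 ± 0.28), Ccdc77 (1.11 ± 0.23), the interferon-induced gene Mx2 (1.10 ± 0.17), Calca, which encodes calcitonin and its gene-related peptide (1.08 ± 0.20), and Tbccd1 (0.96 ± 0.24). Lower were Fcrl2 (-1.47 ± 0.26), Amy1 (-1.31 ± 0.32), Wdr37 (-1.28 ± 0.17), RT1-Bb (-1.23 ± 0.16), Nom1 (-1.10 ± 0.28), the dicarboxylate transporter gene Slc13a3 (-1.09 ± 0.12) and Acsm5 (-1.0034 ± 0.20). Prss35, Calca, Tbccd1 and Nom1 were not called with the pair fitted alone, nor Glra1 and Mx2 with the mean of their probe sets, and a further probe set of Wdr37 gave 0.20. A further probe set kept the sign for Ccdc77 (1.382), Glra1 (0.11), Mx2 (0.16) and Calca (0.16).

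By list, 3 of the 16 candidate genes fell in the arrays labelled AA and none rose: Gsta4 (-0.63 ± 0.18), Creb1 (-0.61 ± 0.13) and Grm2 (-0.61 ± 0.13). The mean of this list was lower by permutation of its array means (-0.17, permutation test, adjusted p = 0.0036), with camera adjusted p = 0.214. Of the glutamate genes, the glutamine synthetase gene Glul (0.39 ± 0.05) and the transporter gene Slc1a1 (0.26 ± 0.05) rose and Grm2 fell, and of 40 glutathione and oxidative stress genes Gsta4, Gstm5 (-0.24 ± 0.07) and Sod1 (-0.14 ± 0.03) fell. The mean of 10 acetylcholine genes was lower (-0.20, permutation test, adjusted p = 0.0222), with none of them called. Both permutation tests exchanged all arrays labelled AA and ANA, which lay in more than 1 set. They were not run within the set that held most of them. Their adjusted p-values cover the pairs and not the lists. RT1-Bb and Tap2 (-0.38 ± 0.08) fell and Mx2 rose among the antigen presentation and interferon genes, whose camera adjusted p was 0.296. No list passed camera in this pair. In all, 326 genes were called, 165 higher and 161 lower in the arrays labelled AA, 50 by at least 1.5-fold. With the pair fitted alone there were 153. With only the 8 and 9 arrays of the set that held most of them, fitted alone and chosen after seeing the data, there were 439 (214 higher, 225 lower), which held 236 of the 326.

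No gene was called between the arrays labelled P and NP by limma (9 and 10 arrays, smallest adjusted p 0.717), with 709 genes at an unadjusted p under 0.05 and 0 with the pair fitted alone. With array weights 1500 genes were called, where 5 of 20 draws of permuted labels gave as many. The largest log2 differences were of neuropeptide genes that were not called, with Tac1, the precursor gene of substance P, at 1.01, and Nts, the neurotensin gene, at 0.83. As whole lists, 13 of 31 shifted by camera, 3 of them with an estimated correlation, and none by fry (smallest adjusted p 0.0543). The mean of array P 10 over 9 forebrain markers was 10.52, against 7.965 to 8.452 in the other arrays labelled P, and its mean over 20 dopamine neuron markers 8.242, against 9.553 to 11.91. Without P 10, a check chosen after seeing the data, the list mean of forebrain genes went from 0.305 to 0.04 (camera adjusted p = 0.845), of opioid genes from 0.361 to 0.07 (0.549), of GABA genes from 0.151 to 0.05 (0.524), of glutamate genes from 0.07 to 0.03 (0.549) and of glutathione genes from -0.05 to -0.005 (0.371). With all arrays these 5 lists had an adjusted p with an estimated correlation of 0.119, 0.161, 0.119, 0.12 and 0.26. The other 8 of the 13 lists kept their call without it, and 4 more were called, which made 12. Of these 4, dopamine neuron markers went from 0.06 to 0.358 (camera adjusted p = 1.46e-08, and adjusted p = 0.141 with an estimated correlation). The array labelled NP 8 (Th 8.23, others labelled NP 11.64 to 14.88) was kept, so a low array was left out on 1 side only. Acetylcholine genes (camera adjusted p = 0.00245), red nucleus and oculomotor markers (0.00384) and thalamic markers (0.0396) were higher as well, each with an adjusted p of 0.0675 with an estimated correlation. The 3 lists with an estimated correlation shifted upward, each with an adjusted p of 0.0412, and none did with 1 array left out in 8 of 19 cases, P 10 among them. Without P 10, stress and feeding neuropeptides went from 0.258 to 0.214 (adjusted p = 0.0675 with an estimated correlation), candidate genes from 0.325 to 0.179 (0.0675) and cyclic AMP genes from 0.116 to 0.03 (0.0907). In the neuropeptide list 32 of 36 members were above 0 with all arrays (median 0.194, fry adjusted p = 0.0543) and 27 without P 10 (median 0.104, fry adjusted p = 0.227). Ion channel (adjusted p = 0.0684 with an estimated correlation, all arrays) and synaptic vesicle genes (0.119) were higher and endothelial markers (0.119) lower by camera with any 1 array left out. Pan-neuronal (0.281) and hypothalamic (0.119) genes were higher by camera, but with 1 of the 19 arrays left out the call held in only 14 and 11 of the 19 cases. The mean of the endothelial markers was also lower by an exact permutation test (-0.10, adjusted p = 0.0419).

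No gene was called between the arrays labelled sP and sNP by limma (8 and 9 arrays, smallest adjusted p 0.9997), with 124 genes at an unadjusted p under 0.05, fewer than the 554 of chance, 0 with the pair fitted alone and 3 with array weights. Immediate early genes shifted downward in the arrays labelled sP by camera (adjusted p = 2.65e-05, and adjusted p = 0.0556 with an estimated correlation). All 11 had differences below 0, of which Klf2 (-0.33), Fos (-0.31) and Nr4a1 (-0.24) were the largest, and none was called. Their mean was lower by an exact permutation test (-0.15, adjusted p = 0.0193), and fry gave an adjusted p of 0.991. Meningeal and fibroblast markers shifted downward too (camera adjusted p = 0.00345, and adjusted p = 0.961 with an estimated correlation), with 13 of 14 below 0. Without array sNP 9, a check chosen after seeing the data, their mean went from -0.179 to -0.02 (camera adjusted p = 0.89), and the call was also lost without sP 4 (0.0855) or sNP 6 (0.0956).

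Averaged over the 5 pairs, each with the same weight, 155 genes were called, 85 higher and 70 lower in the arrays labelled with the high-consumption lines, of which 3 differed by at least 1.5-fold. Of the 5 pairs, P/NP, AA/ANA and sP/sNP entered as labelled, with 3 arrays labelled AA or ANA in sets of other pairs. Whether the labels of all 56 arrays of these pairs match their values is open. This holds for every result over the 5 pairs below. The count was 75 without HAD2/LAD2, 248 without P/NP and 271 without sP/sNP. Among those with the same sign in all pairs, Ncaph was highest (0.53 ± 0.08), followed by the metalloreductase gene Steap4 (0.24 ± 0.06), the phosphatase gene Ptpre (0.23 ± 0.04), the adaptor gene Grb14 (0.22 ± 0.06), the synaptic gene Prrt2 (0.20 ± 0.05), Bloc1s6 (0.18 ± 0.04), the phosphofructokinase gene Pfkl (0.16 ± 0.04), Gtf2e1 (0.15), Rsl1d1 (0.13), Plpp6 (0.11), Lrrc45 (0.11) and Rrp7a (0.11). Lowest were Mis18a (-0.71 ± 0.09), Trak2 (-0.50 ± 0.07), the KIT ligand gene Kitlg (-0.35 ± 0.08), the deoxycytidine kinase gene Dck (-0.31 ± 0.05), Tsc22d2 (-0.29 ± 0.05), Grm2 (-0.27 ± 0.06), Lcnl (-0.24), the caspase gene Casp6 (-0.19), Sync (-0.18), the endothelial receptor gene Adgrl4 (-0.16), Oma1 (-0.14) and B3galt4 (-0.12). Mis18a drew on a difference of -3.22 in HAD1/LAD1, and its difference depended on the pair (limma interaction, adjusted p 1.42e-17). A further probe set of Trak2 gave an average of 0.08, against the sign of the first. Sync had a mean of 0.03 over its probe sets, and Grb14 was not called after quantile normalization. Of the listed genes, RT1-T24-4 (0.95 ± 0.23), RT1-S3 (0.41 ± 0.09), Ifi27 (0.39 ± 0.06) and Glul (0.09) rose and RT1-Bb (-0.51 ± 0.07), Gsta4 (-0.37 ± 0.08), Grm2 and Slco1a4 (-0.10) fell, and no list passed camera. The p-values of this average measure spread between animals. With the 5 pair differences as the observations, limma called 0 genes (340 at an unadjusted p under 0.05, where chance gives 554), and 574 genes, 5.18% of those tested, had the same sign in all pairs, where 6.25% would by chance. The share of higher calls was 54.8% as deposited and 44.4% (72 higher, 90 lower) after quantile normalization.

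The high-minus-low difference depended on the pair in 701 genes by the interaction test, with 1815 at an unadjusted p under 0.05. Grifin spanned the widest range, from -2.38 in HAD1/LAD1 to 1.84 in HAD2/LAD2. Amy1 ran from 2.28 in HAD1/LAD1 to -1.31 in AA/ANA, Fcrl2 from 2.106 in HAD2/LAD2 to -1.47 in AA/ANA, and Ccdc77 from 1.11 in AA/ANA to -0.90 in HAD2/LAD2. The pancreatic lipase gene Pnlip ran from 0.52 in AA/ANA to -1.86 in HAD2/LAD2, the chitinase-like gene Chi3l1 from 1.01 in HAD1/LAD1 to -0.87 in HAD2/LAD2, and Tstd1 from 1.03 in HAD2/LAD2 to -0.60 in AA/ANA.

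In at least 3 pairs only RT1-Bb and Sh3tc2, a gene of peripheral myelination, were called in the same direction, lower in HAD1, HAD2 and the arrays labelled AA (RT1-Bb -0.74, -0.72 and -1.23, Sh3tc2 -0.49, -0.30 and -0.50), where independent lists would give 0.175. Sh3tc2 was named after its values were seen. The count of 2 went to 1 without the filter on dim genes or with a replicate block, to 0 by limma with the filter at the 60th percentile, to 4 with the sets as a term and to 21 with array weights. With calls in only 3 of the pairs none could be called in 4. In at least 2 pairs 94 were called in the same direction, where independent lists would give 26.7. HAD1/LAD1 and AA/ANA shared 35 called genes, 21 in the same and 14 in opposite directions, where independent lists would give 6.29 and 6.27. HAD2/LAD2 and AA/ANA shared 46, with 18 in the same and 28 in opposite directions, where independent lists would give 8.92 and 8.87. Since calls in opposite directions exceeded independent lists too, the excess of the 94 and of the 2 is not by itself agreement in direction. Pearson's r across genes ranged over the 10 pairings of pairs from -0.11 (HAD2/LAD2 and AA/ANA) to 0.08 (AA/ANA and sP/sNP), and none lay outside the values from permuted labels.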

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

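The tests on the order of the last 56 columns and on the wrong label, swapped label and segregating alleles of the array labelled LAD1 37 were chosen only after the results were seen. So was the use of the planned fits of each pair alone as a test of a widened spread. Values far from the rest of their line were sought with Dixon's gap over range, which chance exceeds in about 1 in 20 groups. It was exceeded in 32 of 186 groups: 8 of 50 for array measures, 19 of 96 for named genes and 5 of 40 for dopamine genes.

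The array labelled LAD1 37 lay apart from the other LAD1 arrays at Cyp2j10 (gap over range 0.713), RT1-T24-4 (0.848), Kif15 (0.597), Elavl1 (0.838), Mis18a (0.772), Pla2g4e (0.661), Etfbkmt (0.676), Mgmt (0.533) and Rrs1-ps9 (0.712). Over the genes called without it, it lay at 1.033 on a scale with the LAD1 mean at 0 and the HAD1 mean at 1. A swap of labels within the pair is argued against by the lowest held-out HAD1 array, at 0.8429, and poor RNA by a Gapdh 3'-minus-5' signal of 1.9067, within the 1.55 to 2.139 of the other 17 arrays. It lay nearer the LAD1 mean at 12.35% of the genes, against 13.4% to 27.97% for HAD1 arrays and 74.6% to 93.0% for other LAD1 arrays. A single wrong label may account for this. Whether this array held a mixture of both kinds of alleles at these genes was not decided. Its share of 12.35% lay between the limits set for and against a mixture. The shares are also not measured alike, since this array was scored on 591 genes. The HAD1 arrays were scored on 251 to 306 genes, called with LAD1 37 among the LAD1 arrays. A LAD1 animal with HAD1-like alleles at nearly all called genes cannot be told apart from a wrong label, since no measure of genotype was used here.

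No gene was called between the arrays labelled P and NP or sP and sNP by limma (709 and 124 at an unadjusted p under 0.05), while 3 arrays labelled AA or ANA lay in the sets of other pairs. With each pair fitted alone the count was 0 in both, which argues against a spread widened by arrays of other sets. When the labels of the last 56 columns were rotated against their values, the only rotation that put each pair in 1 set, by 19 places, called 1468 genes over the 3 pairs (341, 665 and 462). The next highest of the 56 rotations called 1097 (20 places), the median 147 and the labels as given 326. A candidate explanation is that these columns are stored in another order than their labels, which stays a hypothesis. Apart from the rotation counts, no value in the report uses another order. All results of P/NP, AA/ANA and sP/sNP and their overlaps with other pairs rest on these labels as given. So do the average over the 5 pairs, the share of genes with the same sign and the interaction.

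Further values of the gap over range were 0.518 for the median, 0.485 for the interquartile range, 0.499 for the Gapdh signal and 0.558 for the actin signal of the array labelled AA 1, 0.551 for the median of sNP 4, and 0.474 for the Gapdh signal of LAD1 36. The mean correlation with the line gave 0.803 for P 10 and 0.536 for sP 2. The array labelled ANA 20 stood apart at Prss35 (0.774), Mx2 (0.468), Tbccd1 (0.508), Fcrl2 (0.711), RT1-Bb (0.508) and Slc13a3 (0.597). Others were HAD1 25 at Rrs1-ps9 (0.538), HAD2 8 at Trak2 (0.553), ANA 6 at Wdr37 (0.554) and AA 5 at Slc13a3 (0.677). Of the dopamine genes, Th gave 0.567 for HAD2 5 and 0.512 for NP 8, Slc6a3 0.54 for NP 8 and 0.47 for ANA 6, and Slc18a2 0.535 for LAD2 20.

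The difference depended on the pair in 701 genes, and between the HAD/LAD pairs in 459. The range of the 5 log2 differences was 4.22 for Grifin, 3.59 for Amy1, 3.57 for Fcrl2, 3.47 for Elavl1, 2.46 for Pkp1, 2.38 for Pnlip, 2.02 for Ccdc77, 1.88 for Chi3l1, 1.78 for Etfbkmt and 1.63 for Tstd1.

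Among 100 splits of the arrays within pairs, the real one included, a chance division of the animals is argued against for HAD1/LAD1 (427 genes, 1 split as large, highest other 72) and HAD2/LAD2 (605, 1 split, 201). These splits exchange animals, so they show only that the lines of a pair differ. With 1 line per direction in a pair, they cannot tell selection from other differences between the lines. The count of the arrays labelled AA and ANA (326 genes) was reached in 1 of the 100 splits, the real one (highest other 310), but it was 153 with the pair fitted alone and 239 without AA 15, and 7 of the other rotations of labels gave 331 to 665. The average (155 genes) was reached in 2 of the 100 splits, the real one included (highest other 393), and the interaction (701 genes) in 4 (highest other 1723). For the arrays labelled P and NP (0 by limma and 709 unadjusted, highest other 4831) and sP and sNP (0 by limma and 124 unadjusted, highest other 5), all 100 splits are as large as a count of 0 by construction, which says nothing about chance. For the genes called in at least 3 pairs (2, 1 split, highest other 0) the splits also remove the differences within pairs, so they say nothing about chance agreement between pairs. Independent lists give 0.175, but calls in opposite directions exceeded independent lists too (59 against 11.4 between the HAD/LAD pairs). The 0.175 is therefore no measure of chance agreement in direction. A split of the arrays labelled P and NP with 4831 genes, and splits with 1723 and 393 genes for the interaction and the average, all above the real counts, point to a structure of the samples, so the 2 and 4 splits, and that of the arrays labelled AA and ANA, are given here without a conclusion.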

How the results depend on the processing

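Leaving out arrays for the pairs and lists, the model with the 5 sets and the average of both HAD/LAD pairs were chosen after seeing the data. Of 1466 recomputations of 141 named values, 1403 kept their side of the threshold, and their direction where the value was called in the fit of all arrays. Of the rest, 59 lost the call, 2 gained it (Ddc in HAD1/LAD1) and 2 reversed. For values not called in that fit, such as those of Th, a change of direction was not counted. With the mean of the probe sets, the Sync average became 0.03483 and Dlg4 HAD1/LAD1 -0.007141. Probe sets that differ would do this by construction. Where no cause is named, the cause was not tested.

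Array weights gave 742 (HAD1/LAD1), 971 (HAD2/LAD2), 1500 (P/NP), 981 (AA/ANA), 3 (sP/sNP), 911 (average), 2903 (interaction) and 21 genes (at least 3 pairs). Permuted labels gave as many in 5 of 20 draws for P/NP (highest 3785) and 6 for sP/sNP (highest 109). All probe sets, more features by construction, gave 1042, 1302 and 835 (HAD1/LAD1, HAD2/LAD2, AA/ANA), 455 (average), 1749 (interaction) and 13 (at least 3 pairs). The 1.5-fold threshold, stricter by construction, left 70, 105, 50, 3, 304 and 1. AA/ANA fitted alone gave 153. The average gave 75 without HAD2/LAD2, 248 without P/NP, 271 without sP/sNP, 76 in an additive model, 573 over both HAD/LAD pairs and 0 with pair differences as observations (limma, 340 unadjusted). Genes called in at least 3 pairs were 1 without the filter, 0 by limma at the 60th percentile and 4 with sets as a term, against 94 in at least 2 pairs and 0 in at least 4 or at least 5, which calls in only 3 pairs fix. Of 17 list calls, 3 held with an estimated correlation and 1 by fry, and without LAD1 37 or without P 10 there were also 17, not all the same lists in the latter case.

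Leaving out 1 array gave 144 to 188 genes for the average, 361 to 580 for HAD1/LAD1, 516 to 671 for HAD2/LAD2, 239 to 485 for AA/ANA, and 0 throughout for P/NP and sP/sNP by limma (709 and 124 unadjusted with all arrays). Animal numbers are shared in P/NP and sP/sNP, and with the labels as given they showed no pairing of the samples. Correlations of same-numbered arrays ran from -0.739 to 0.733 and from -0.371 to 0.291, and 1 of 9 and 0 of 8 correlated best with their own number. If these columns are stored in another order than their labels, the check could not have found a pairing. A replicate block gave 17 genes for P/NP and 1 in at least 3 pairs. Not run were each pair alone for the average, interaction and lists, and the fold threshold for correlations and lists. Signal over background limits dim genes: 11082 of 14217 passed the filter.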

Other observations

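The tests of sequence variants and of direction were chosen only after the result was seen, and that of neighbouring genes before. Calls of HAD1/LAD1 and HAD2/LAD2 overlapped in 118 genes, with 59 in the same and 59 in opposite directions, against 11.9 and 11.4 for independent lists. No excess of genes that went the same way was seen, with 50% in the same direction (exact 95% interval 40.7 to 59.3). The interval treats the genes as independent, which neighbouring genes are not, so it is too narrow. Selection that moves the same genes the same way cannot by itself give the 59 genes in opposite directions. How far it contributed to the other 59 was not decided. Neighbouring genes inherited together may account for part of it: 8 neighbouring pairs of tested genes were both in the overlap, against at most 7 in 10000 random placements (p = 1e-04, the smallest they can give). The calls of each pair alone clustered too, with 48 neighbouring pairs in HAD1/LAD1 (mean of random placements 16.3) and 59 in HAD2/LAD2 (33), each with p = 1e-04 by random placement. An overlap of 2 clustered lists would also pass, so the test shows nothing particular to the overlap. Near-identical copies such as RT1 genes were not set apart. For sequence variants under single probe sets the test decides nothing. In the 26 overlap genes with another probe set above the floor, its difference was a median of 0.164 of the first (95% bootstrap interval -0.05 to 0.441), but the first probe set was the one chosen by its calls and is by rule the brighter one, which alone lowers this ratio. The explanation by neighbouring genes stays a hypothesis, and shared founders of the HAD/LAD lines were not tested.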
